A study of Mus musculus with 2 samples.

How the data were processed

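DNase-seq cuts nuclear DNA with the enzyme DNase I, which reaches open chromatin first, and sequences the cut ends. Adrenal gland tissue of male B6CASTF1/J mice, an F1 hybrid strain, was measured at the age of 2 months. The series holds 2 libraries, which the labels give as biological replicates 1 and 2, and both belong to 1 group. With 1 group no contrast between conditions could be made, so each replicate was described and set beside the other.

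The authors deposited 2 peak lists, 1 footprint list and 1 track of cut-rate FDR for each library, on the mouse build mm10. Each list was derived from the filtered alignments of a single library, per the file list deposited with the sample, so peaks were called per replicate and not on pooled reads. The aligner, the peak caller, the footprint caller and their thresholds are not given in the sources used here. The deposited peak height is a signal, the height of a coverage track, and its scaling factor is not stated. Heights below 1 were whole multiples of 1 step per library, within a tolerance of 0.05 of a step, and that step was 0.00382 in replicate 1 and 0.00458 in replicate 2. The deposited FDR track holds a q-value per interval and lists only intervals below 0.05. The deposited footprint list carries the same value, 0.01, in every line, which is a threshold and not a p-value per footprint. The summit column held the same offset, 75, in every line, so the centre of a peak was used. Read totals were not used here, so the depth per sample is unknown and is described only by the number of peaks, the listed length and the height step.

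The shorter peak list of each library was the main list and the longer list an alternative. The plan had named the list with narrower intervals, but the median width was 200 bp for both lists of replicate 1, so the shorter list was chosen after widths and lengths were seen. Every peak of the shorter lists reached an FDR of at most 0.001 in the track of its own library. Overlapping entries of a list were merged into 1 region with the highest height, which left 72643 of 74084 entries in replicate 1 and 157649 of 159106 in replicate 2. Heights were used to rank and describe, as percentiles within a library or as log2 ratios between replicates.

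Peaks of both replicates were compared by overlap of at least 1 bp, counted with an interval search in numpy whose totals were checked against bedtools 2.31.1. Random overlap came from 100 seeded placements of the peaks within their chromosomes, and random location from 10. Shares of peaks carry 95% Wilson intervals, which cover counting error only. The annotation was GENCODE vM21, and transcript starts came from its basic transcripts. A peak within 500 bp of any such start was a promoter peak, and every other peak was distal. The remaining classes were exon, intron and intergenic, in that order of priority.

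Gene lists were fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. They held 339 members in 25 lists: steroid hormone synthesis, cortex regulators, zona glomerulosa, inner cortex and X zone, capsule and stroma, chromaffin cells, Schwann and glial cells, endothelium, macrophages, T and B lymphocytes, erythroid cells, white and brown fat, kidney tubule, liver, brain neurons, skeletal muscle, lens, testis germ cells, pancreas, keratinocytes, cholesterol synthesis and uptake, immediate early genes, circadian clock, glucocorticoid response and broadly expressed genes. A list of olfactory receptors that the plan mentioned was not made. Of 340 entries, 1 had no match in the annotation (Amy2b) and 1 was matched by a synonym (Bmal1, annotated as Arntl). For each list the share of genes with a promoter peak was set against 10000 seeded random lists drawn from the 21755 protein coding genes of the autosomes and the X, of the same size and matched on decile of promoter CpG observed over expected. The median number of distal peaks in a 100 kb window around the gene's outermost end was tested in the same way, with matching on gene density. Both are two-sided resampling tests with Benjamini-Hochberg adjustment over the 25 lists, and the smallest unadjusted p they can give is 0.0002. A list was called where both replicates passed 0.05 in the same direction. Genes are not replicates, so these p-values describe the libraries and not a population of mice. A promoter peak at any transcript start of a gene counted, and the number of starts per gene was not matched.

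The gene record can reach beyond the basic transcripts. For 1305 of 21755 genes the outermost end of the record lay over 500 bp from any basic start, so CpG matching and windows were also computed at the outermost basic start, as an alternative chosen after the data were seen.

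Consensus motifs, 30 in number, were searched on both strands within 75 bp of the centre of distal peaks and in 150 bp windows 1000 bp to each side. The odds ratio was divided by the median odds ratio of 20 shuffles of the same motif with the same number of CpG, and a motif was called where it exceeded all 20 in both replicates. The SP/KLF motif has only 7 such shuffles and was not judged. A motif occurrence counted as footprinted where a footprint covered at least 50% of its bases. The footprinted share was compared with that of the shuffled motifs by Fisher's exact test per replicate, with Benjamini-Hochberg adjustment over motifs. This test pools all shuffles and treats occurrences as independent, so its p-values cover counting error and not the spread between shuffles.

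The named genes followed a rule written in advance. Per list they were the first 4 members in the order of the list, the members with the highest and the lowest promoter peak by mean percentile, and at most 3 members with a promoter peak in 1 replicate only. Genome-wide they were the 10 peaks with the highest mean percentile, the 5 genes with the most distal peaks, the 3 called motifs with the largest corrected odds ratio and every called nuclear receptor motif. Some genes and motifs that the rule names are left out of the text and the plots.

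The list tests, the motif and footprint counts, the overlap count and the height ratios were tested on simulated data, and the location of peaks was not. Of 200 simulated lists of 15 genes with no effect, matched on simulated deciles, 2.0% had p below 0.05, against 38.0% without matching. Of 200 lists planted at 90% open, 100% passed. Decile labels were random, the open rates per decile were set values, and the lists came from the lower deciles. For distal peak numbers, 3.0% of 200 lists with no effect passed with matching on simulated deciles of gene density, and 13% without. Of lists planted at 3 times the mean, 92.5% passed. In both list tests, passing meant an unadjusted p in a single simulated data set, so these shares test the procedure and not the calls. Planted deviations of height ratios were found within 0.0476 on the log2 scale over 20000 pairs. All 3 planted motifs were called, with a largest gap of 0.0585 points between found and expected shares in 20000 windows. The planted footprint share was recovered within 0.196 points over 5000 windows, and 0 of 800 intervals had an overlap count that differed from a direct count.

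Alternatives were another overlap rule, peaks above the median height, the longer lists, equal numbers of strongest peaks, other promoter and motif windows, unmatched random lists, other footprint overlaps and leaving out each replicate. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Sequence variants between the parental strains, reads and alleles were not analysed here, because the deposited lists carry no allele.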

Results

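Open chromatin was mapped by DNase-seq in adrenal gland tissue of male B6CASTF1/J mice at 2 months of age. The gland has a cortex that makes steroid hormones and a medulla of chromaffin cells that make catecholamines. The series held 2 libraries, biological replicates 1 and 2 of 1 group. Replicate 1 had 72643 peaks over 15.5 Mb (0.586% of the sequenced genome), and replicate 2 had 157649 peaks over 31 Mb (1.17%). Read totals were not used here, so the depth per sample is unknown. The track of low FDR listed 40.1 Mb in replicate 1 and 76.2 Mb in replicate 2. The median peak height was 0.863 in replicate 1 and 0.861 in replicate 2, in the authors' units, and the highest peaks reached 60.8 and 75.2.

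Genes that make and regulate cortical steroids were more often open at their promoters than matched genes, and genes of lymphocytes and of testis germ cells less often. Genes for fat cells and for the glucocorticoid response were also open more often. Genes of the chromaffin cells of the medulla were open about as often as matched genes. The comparison asked which cell types' genes carried promoter peaks in the gland. Of 21755 protein coding genes, 13280 (61.0%) had a promoter peak in replicate 1 and 14328 (65.9%) in replicate 2, and 13200 had one in both. Promoters in the lowest CpG decile were open in 6.11% and 10.4% of cases and those in the highest in 96.8% and 97.4%, which is why lists were matched on CpG.

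Of the steroid synthesis genes, 12 of 15 had a promoter peak in replicate 1 and 15 of 15 in replicate 2. The matched random lists averaged 48.2% and 54.5%, and the adjusted resampling p was 0.018 and 0.00167. Star, which brings cholesterol into mitochondria, had a promoter peak at chromosome 8, 25808301 to 25808620, with a height of 2.71 in replicate 1 and 5.21 in replicate 2. Cyp11a1, which cuts the cholesterol side chain, had heights of 3.08 and 5.97 at a start inside the gene. Cyp21a1, the 21-hydroxylase, had heights of 1.12 and 3.53. Por, which passes electrons to microsomal P450 enzymes, had the highest promoter peak of the list, at a mean percentile of 99.5 ± 0.431 (SD, n = 2). Hsd3b1, which makes progesterone from pregnenolone, had the lowest value, with no peak in replicate 1 and a height of 0.321 in replicate 2. Hsd3b6, a zona glomerulosa relative of that enzyme, and Cyp11b2, the aldosterone synthase, also had a promoter peak in replicate 2 only. The call of this list was lost with unmatched random lists and when only the outermost end of the gene counted (70.0% with a peak).

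All 18 cortex regulators had a promoter peak in both replicates, against matched means of 62.6% and 68.4% (adjusted resampling p 0.005 and 0.00167). Nr5a1, the main transcription factor of steroid cells, had heights of 2.74 and 5.42. Mc2r, the receptor for the pituitary hormone ACTH, had heights of 0.546 and 1.56, and its partner Mrap had 3.27 and 7.05. Nr0b1, an X-linked repressor of Nr5a1 activity, had the lowest values, 0.244 and 0.389. Cited2, a coactivator needed for adrenal development, had the highest, 7.58 and 13.8.

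Genes that mark zones and the capsule were open in most cases, without a call. A promoter peak was present at 10 and 11 of 13 zona glomerulosa genes in replicates 1 and 2, at 7 and 8 of 9 genes of the inner cortex and X zone, and at 8 and 11 of 13 capsule and stroma genes. The angiotensin receptor gene Agtr1a had heights of 3.18 and 5.12 and its paralog Agtr1b 0.516 and 1.02. Dab2, an adaptor protein of the glomerulosa, had 2.38 and 5.00, and the potassium channel gene Kcnk9 had no promoter peak. Akr1c18, the classical enzyme of the X zone that regresses in males at puberty, had no promoter peak, while Pik3c2g, another X zone gene, had heights of 0.424 and 1.11. Akr1b7, a reductase of the zona fasciculata, had 1.07 and 2.20, and the thyroid hormone receptor gene Thrb had 3.45 and 5.02. Cyp2f2, a P450 gene, was open in replicate 2 only. In the capsule list, the hedgehog effector Gli1 had heights of 2.05 and 3.88, its pathway receptor Ptch1 3.41 and 5.73, the Wnt enhancer Rspo3 0.435 and 0.595, and the nuclear receptor gene Nr2f2 1.19 and 1.77. The stromal factor genes Tcf21 and Wt1 and the matrix gene Dcn were open in replicate 2 only, and the matrix gene Lum in neither.

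Of 20 chromaffin genes, 14 and 15 had a promoter peak, beside matched means of 70.3% and 75.8% (adjusted resampling p 1.00 in both). Th, which makes the catecholamine precursor, had a peak in replicate 2 only, with a height of 0.513. Dbh, which makes noradrenaline, had heights of 0.726 and 1.03, and Chga, the granule protein chromogranin A, had 0.917 and 1.81. Pnmt, which makes adrenaline, had no promoter peak. Slc18a1, the vesicle transporter of catecholamines, had the highest peak, 7.4 and 14.8. The transcription factor gene Phox2a had a peak in replicate 1 only and Hand2 in replicate 2 only. Among peaks above the median height the list was called lower, with a mean of 30.0% of genes.

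Other cell types that a dissected gland can hold gave mixed results. Of 12 genes of white and brown fat, 9 and 12 had a promoter peak, against matched means of 42.0% and 48.8% (adjusted resampling p 0.0437 and 0.00167). Cox7a1, a mitochondrial subunit of brown fat and muscle, had heights of 3.88 and 9.85. Ucp1, the uncoupling protein, had 0.775 and 1.58, the lipid droplet gene Plin1 0.863 and 2.84, and the fat regulator Pparg 0.928 and 1.53. The hormone gene Adipoq, the lipid droplet gene Cidec and the deiodinase gene Dio2 were open in replicate 2 only. The call of the fat list was lost with promoters of 1000 bp, with unmatched lists and among peaks above the median height. Endothelial genes had a promoter peak in 11 and 15 of 15 cases (adjusted resampling p 0.331 and 0.00167), a call in replicate 2 alone. The vessel genes Cdh5, Kdr and Tek were open in both replicates, at heights of 0.986 and 1.30, 1.69 and 2.31, and 0.432 and 0.669. Pecam1, Plvap and Erg were open in replicate 2 only. Esam, an adhesion gene, was highest at 1.63 and 2.89, and Sox17, an arterial factor, lowest at 0.374 and 0.508.

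Of the blood and glial lists, only that of lymphocytes was called at promoters, as lower. Macrophage genes had a promoter peak in 2 and 6 of 12 cases, erythroid genes in 1 and 2 of 10 and Schwann cell genes in 4 and 4 of 9, without a call. The monocyte genes Cd14 and Cd68 were open in both replicates, Adgre1, C1qa and C1qb in replicate 2 only, and the lineage genes Csf1r and Spi1 in neither. The receptor gene Epor of erythroid cells was open in replicate 2 only, and Klf1, Hba-a1 and Hbb-bt in neither. In the Schwann cell list, the receptor gene Erbb3 had heights of 1.29 and 1.69. Foxd3 was open in replicate 1 only, S100b in replicate 2 only, and Sox10 in neither. Of 12 lymphocyte genes, 1 was open in each replicate, against matched means of 45.1% and 52.5% (adjusted resampling p 0.00875 and 0.00167). That gene was Bcl11b, a T cell factor also used in other tissues, while Cd3e, Cd79a and Cd4 were closed. The lymphocyte call was lost when only the outermost end of the gene counted (12.5%).

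Of the lists of tissues outside the gland, only that of testis germ cells was called at promoters, as lower. In testis germ cells, 1 of 13 genes was open in each replicate, against matched means of 51.4% and 58.5% (adjusted resampling p 0.005 and 0.00167). That gene was Dazl, an RNA-binding protein of germ cells, with heights of 4.50 and 7.87, while Ddx4, Prm1 and Prm2 had no peak. Kidney tubule genes were open in 3 and 1 of 14 cases (adjusted resampling p 0.301 and 0.00214), brain neuron genes in 4 and 7 of 13 (0.025 and 0.290), and lens genes in 2 and 2 of 13 (0.0954 and 0.0228), each past the threshold in a single replicate. Liver genes were open in 0 and 1 of 13 cases, skeletal muscle genes in 3 and 6 of 12, pancreas genes in 2 and 3 of 11 and keratinocyte genes in 1 and 1 of 10, without a call. The water channel gene Aqp2 of the kidney had heights of 0.672 and 0.971, the uptake receptor gene Lrp2 was open in replicate 1 only, and Slc34a1, Umod and Slc12a1 were closed. Alb, Apoa1, Ttr and Serpina1a of the liver were closed and Cyp2e1, a P450 gene, was open in replicate 2 only. The neuronal factor genes Neurod6, Neurod2 and Tbr1 were closed, and Slc17a7, Gad2 and Camk2a were open in replicate 2 only. The muscle genes Ckm and Mylpf were open in both replicates, Acta1, Myh1 and Tnnt3 in replicate 2 only, and Myod1 and Myog in neither. In the lens list Crybb1 had heights of 1.93 and 5.11, and Crygs, Cryaa and Cryba1 were closed. The islet factor gene Nkx6-1 was open in both replicates, Ins2 in replicate 2 only, and Ins1, Pdx1 and Ptf1a in neither. The skin keratin gene Krt10 had heights of 3.60 and 6.71, and Krt5, Krt14 and Krt1 were closed.

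Genes that respond to hormones and stress were open throughout. All 12 glucocorticoid response genes had a promoter peak in both replicates, against matched means of 63.3% and 69.0% (adjusted resampling p 0.00875 and 0.0228), and this call was lost when only the outermost end of the gene counted (70.8%). Ddit4, a stress-induced inhibitor of growth signalling, was highest at 9.48 and 17.1, and the receptor chaperone gene Fkbp5 had 8.12 and 13.6. The kinase gene Sgk1 had 6.43 and 11.9, and Tsc22d3, an anti-inflammatory mediator on the X, was lowest at 1.65 and 3.88. All 15 immediate early genes and all 15 clock genes were open in both replicates, without a call, since matched genes were open in most cases too. The immediate early genes Jun, Egr1, Fosb and Fos had heights of 8.69 and 17.4, 6.86 and 13.8, 3.67 and 7.74, and 3.45 and 5.00, and Egr3 was lowest at 1.65 and 3.26. The clock genes Nr1d1, Per1, Per2, Arntl and Clock had 8.89 and 18.6, 8.01 and 16.1, 6.17 and 11, 5.91 and 12.1, and 3.44 and 5.98, and Npas2 was lowest at 0.959 and 1.06. Cholesterol genes had a promoter peak in 19 of 20 cases in both replicates, without a call. Dhcr7, the last enzyme of the pathway, had 8.39 and 17.9, and the enzyme genes Hmgcs1 and Sqle were open in both replicates too. Broadly expressed genes, such as Actb, Gapdh, Tbp, Hprt and Rplp0, were open in 20 of 20 cases (adjusted resampling p 0.0437 and 0.115).

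**Figure D1:**
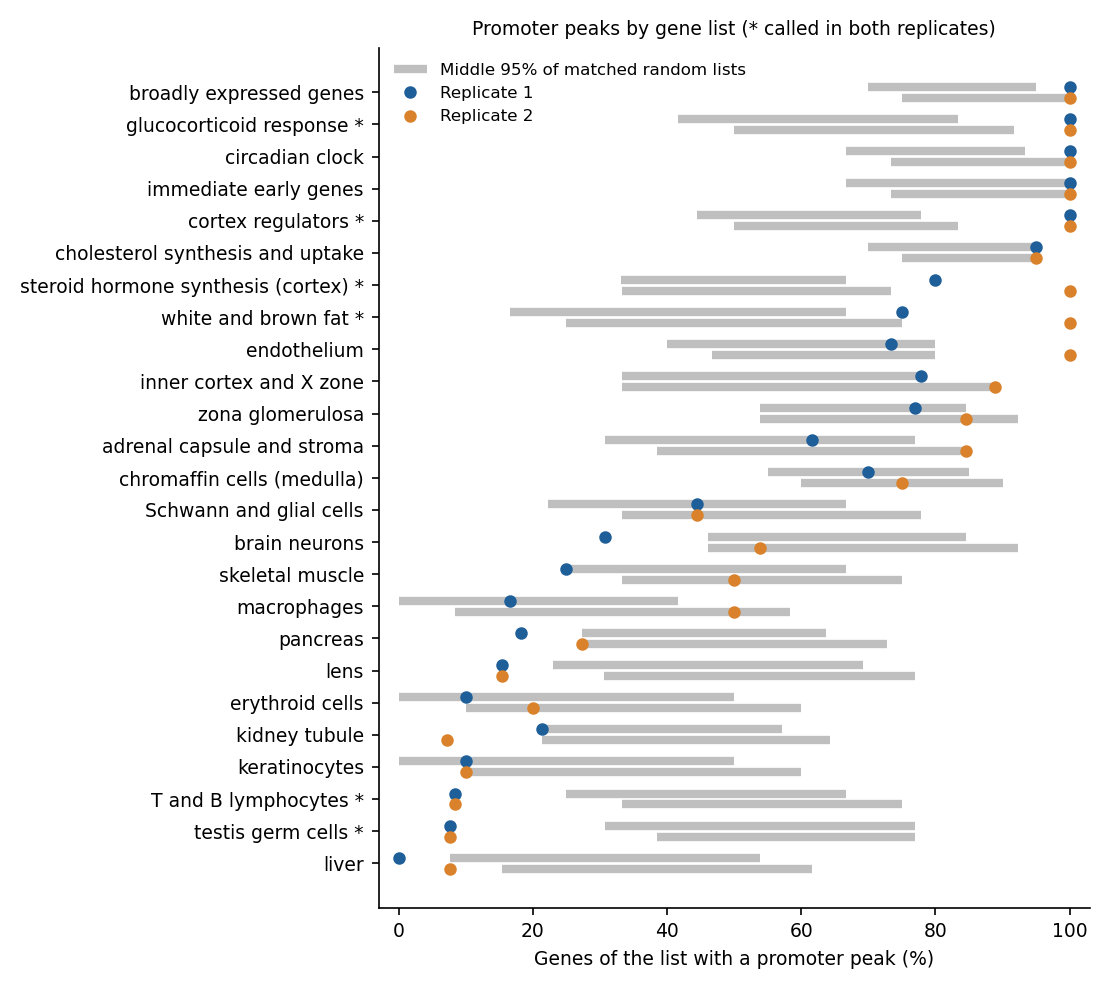
Share of the genes of each list with a promoter peak (percent, x axis), with blue points for replicate 1, orange points for replicate 2 and grey bars for the middle 95% of matched random lists. The steroid synthesis list lies at 80% and 100%, to the right of both bars, and the testis germ cell list lies at 7.69% in both replicates.

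Distal peaks were called more numerous than around matched genes for steroid synthesis genes, immediate early genes and glucocorticoid response genes. A median of 10 and 22 distal peaks in replicates 1 and 2 surrounded the steroid synthesis genes, against 3 and 7 for matched lists (adjusted resampling p 0.0025 in both). Cyp11a1 had 23 and 26 distal peaks within its 100 kb window, Star 7 and 26, Hsd3b1 5 and 26 and Cyp21a1 10 and 15. Immediate early genes had a median of 9 and 15, against 3 and 7 (adjusted resampling p 0.0025 in both), with 6 and 19 around Fos. Glucocorticoid response genes had 7 and 13, against 2.5 and 6.5 (adjusted resampling p 0.00875 and 0.0187), a call lost with the longer peak lists and, in a test chosen after the data were seen, with windows centred on the outermost basic transcript start. Clock genes passed in replicate 1 alone (8 and 12, adjusted resampling p 0.00667 and 0.0821). Lists that passed in replicate 2 alone included cortex regulators (5 and 12, adjusted resampling p 0.058 and 0.0183) and fat genes (4.5 and 12.5, 0.484 and 0.0483). Broadly expressed genes had the same medians as cortex regulators, 5 and 12. Chromaffin genes had a median of 2 and 5.5, against 2 and 6.5. No list was called lower, and without replicate 1 the number of lists called higher was 6 instead of 3. Windows of neighbouring genes in a list can share peaks, and the random lists did not take this into account.

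The window around Star showed how these peaks lay along a locus. Replicate 1 had 11 peaks and replicate 2 had 30 between positions 25756555 and 25856555 of chromosome 8, which also holds Bag4, Lsm1, Ash2l and the start of Kcnu1. The promoter peak of Star covered the start of its basic transcript at 25808474. The gene record begins at 25806555, next to a peak with heights of 2.70 and 5.79 that counted as distal. The extended NR5A1 motif matched in 2 of the 30 peaks of replicate 2 and in 0 of the 11 of replicate 1. All 3 matches lay in a footprint, and none lay in the Star promoter peak. Only exact matches to the consensus were counted, so a site that differs from it would be missed.

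**Figure D2:**
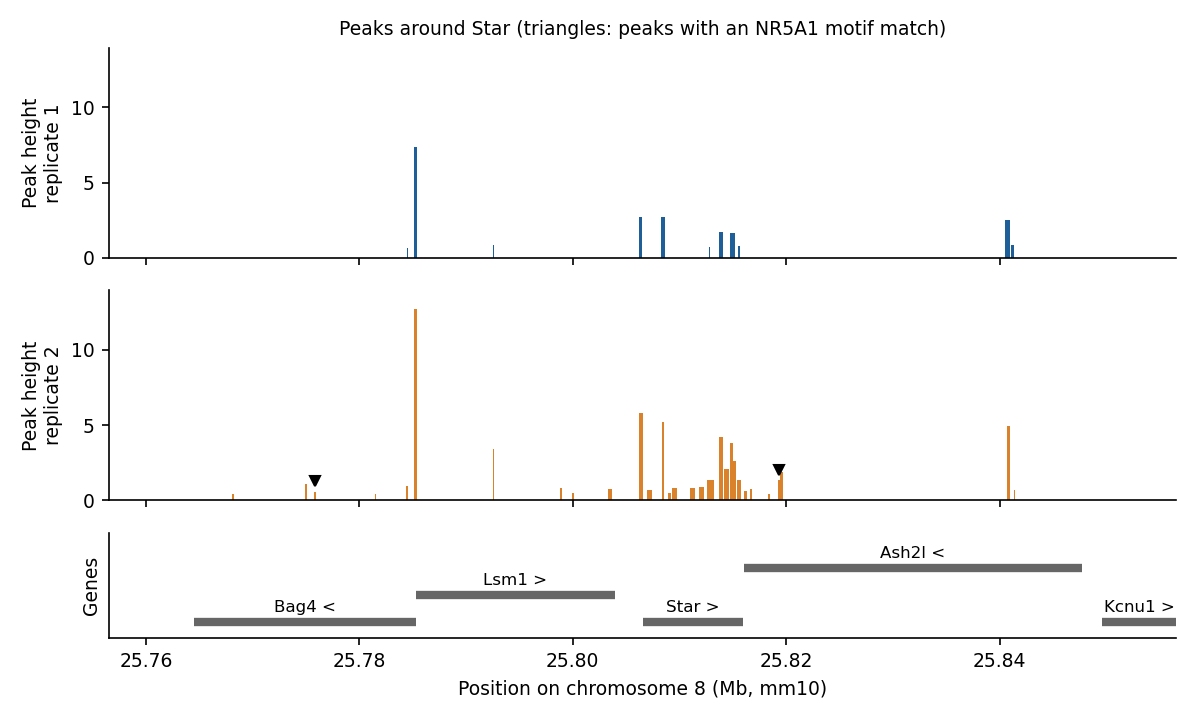
Peaks in the 100 kb window around Star on chromosome 8 (x axis, Mb, mm10), with bars for peak height in the authors' units in replicate 1 (blue) and replicate 2 (orange), triangles for peaks with an NR5A1 motif match and grey lines for genes. The tallest peak, 7.35 in replicate 1 and 12.7 in replicate 2, lies over the adjoining starts of Bag4 and Lsm1.

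The richest windows and the highest peaks lay elsewhere. Among the genes with the most distal peaks in 100 kb were Hoxb5, a body axis gene (43 ± 4.24, SD, n = 2), the potassium channel gene Kcnk3 of the glomerulosa (37.5 ± 7.78), the predicted gene Gm21887 near the end of the X (37.5 ± 12) and Bahcc1, a chromatin reader (35.5 ± 13.4). The highest peak of both replicates, 60.8 and 75.2, lay at chromosome 17, 39846781 to 39846920, in CT010467.1 and 107 bp from the start of Gm42418. The next were in Lars2, a mitochondrial tRNA synthetase gene (33.7 and 42.0), in Kpna1 at Gm15564 (26.6 and 50.3), in Il31ra, a cytokine receptor gene (26.3 and 38.8), and in an intergenic region 18330 bp from Gm43980 (24.2 and 45). The other members of the top 10 lay near Gm25352, at the start of Dynlt1b, 35530 bp from Pak3, at the start of Hjurp and at the start of 2610005L07Rik. Sequence copies elsewhere in the genome were not analysed here, so heights in such regions are uncertain.

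Motifs of CTCF, NFI, REST and some nuclear receptors were among those called at the centre of distal peaks. The question was which transcription factors' motifs had a higher odds ratio there, against the flanks, than shuffled motifs. Of 29 motifs judged, 15 were called in both replicates, over 52021 distal peaks in replicate 1 and 130927 in replicate 2. CTCF, which holds chromatin loops, was present in 8.05% and 4.70% of distal peaks and in 0.150% and 0.134% of flanks, with a corrected odds ratio of 31.2 and 23.4. NFI, a family active in many epithelia, had corrected odds ratios of 10.5 in both. REST, a repressor of neuronal genes, was present in 97 of 52021 distal peaks against 1 of 104042 flanks in replicate 1, and in 200 of 130927 against 2 of 261854 in replicate 2. Its corrected odds ratio, 98.7 as a geometric mean, rests on so few flanks and shuffles that its size is uncertain.

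The NR5A1 motif was called with 5.54% and 7.11% of distal peaks against 1.86% and 1.79% of flanks, and its corrected odds ratio was 2.49 and 3.28. The call was lost among peaks above the median height, where the corrected odds ratio was 2.56. The other called nuclear receptor motifs were those of NR4A, a family induced by ACTH (2.37 and 2.64), of the glucocorticoid receptor (2.19 and 1.98) and of the oestrogen receptor (2.30 and 2.80). The oestrogen receptor motif was found in only 13 and 48 peaks, and its call was lost with every other window or flank and among peaks above the median height. Further called motifs, named after their values were seen, were C/EBP (10.2 and 9.37), AP-1 (6.34 and 6.70), RFX, CREB, MEF2, GATA, STAT and NFY. C/EBP was present in only 0.0750% and 0.0840% of distal peaks and RFX in 0.0615% and 0.0611%, against 13.6% and 14.9% for AP-1. GATA exceeded its shuffles, which were depleted, but in replicate 1 it was not richer than in the flanks (1.70% against 1.69%, and 2.22% against 1.81% in replicate 2). RFX lost its call among peaks above the median height, STAT with 50 bp and NFY with 150 bp around the centre. The motifs of PHOX2, SOX and the E-box of NEUROD type were not called, nor were TEAD, RUNX, ETS, PU.1, LEF/TCF, EGR, NRF1, HNF1, HNF4A or the direct repeat of PPAR and HNF4.

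**Figure D3:**
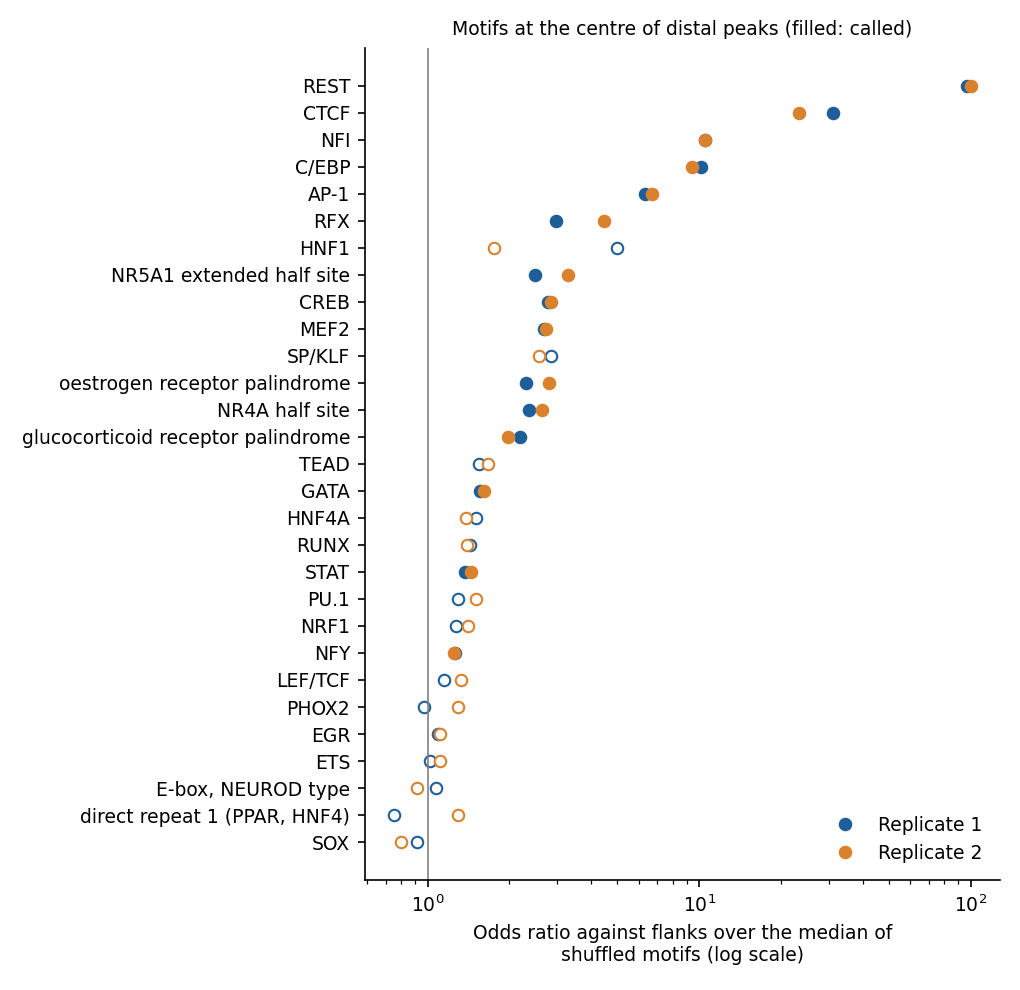
Odds ratio of the motifs shown at the centre of distal peaks against flanks, divided by the median of its shuffles (log scale), with blue for replicate 1, orange for replicate 2 and filled points for called motifs. REST and CTCF lie highest, and the NR5A1 motif lies at 2.49 and 3.28.

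Footprints lay over most occurrences of the CTCF, NFI and REST motifs and over a smaller part of those of NR5A1 and NR4A. The glucocorticoid receptor motif was not called different from its shuffles. Replicate 1 had 287308 footprints and replicate 2 had 541481, with median lengths of 9 and 10 bp. Of these, 64.4% and 71.8% lay in peaks, and 84.7% and 87.6% of peaks held at least 1. CTCF occurrences in distal peaks were footprinted in 96.0% and 95% of cases, against 29.6% and 33.6% for its shuffles. NFI had 88.9% and 90.3%, against 18.5% and 21.0%, and REST had 88.9% and 93.1%. The NR5A1 motif had 38.0% and 50.9%, against 18.3% and 21.1%, with an adjusted p of 2.27e-118 by Fisher's exact test in replicate 1 and a p too small to be represented in replicate 2. In replicate 1, 1 of its 20 shuffles had a higher share, 56.2%. With the whole motif inside the footprint, the NR5A1 shares fell to 16.4% and 29.1% and the NR4A shares to 7.14% and 12.8%, and both calls were kept. The NR4A motif had 22.4% and 30.7%, against 10.8% and 14.6%, with 1 shuffle above it in each replicate (24.5% and 33.9%). The direct repeat of PPAR and HNF4 had 83.3% and 62.5%, over only 6 and 24 occurrences, and its call was lost with either other overlap rule. The glucocorticoid receptor motif had 10.5% and 16.2%, against 13.8% and 16.6%, with adjusted p 0.114 and 0.838 by Fisher's exact test, and its mean difference turned from -1.82 to 1.90 points, without a call, when an overlap of 1 bp was enough. By Fisher's exact test against pooled shuffles, 20 motifs had a higher share and 4 a lower one, among them GATA, PU.1 and TEAD. Of the higher ones, AP-1, CREB, C/EBP, CTCF, NRF1, RFX, NFI and LEF/TCF exceeded all 20 shuffles in both replicates. SP/KLF, REST and the direct repeat had too few shuffles or shuffled occurrences to be judged in this way. EGR lost its call with either other overlap rule and HNF4A with the whole motif inside the footprint. Single shuffles spread around the 3 lower ones named, since GATA exceeded 7 and 8 of its shuffles, PU.1 3 and 2, and TEAD 10 and 13. TEAD had 13.4% and 17%, against 15.1% and 18.3%, and its difference changed sign when an overlap of 1 bp was enough.

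**Figure D4:**
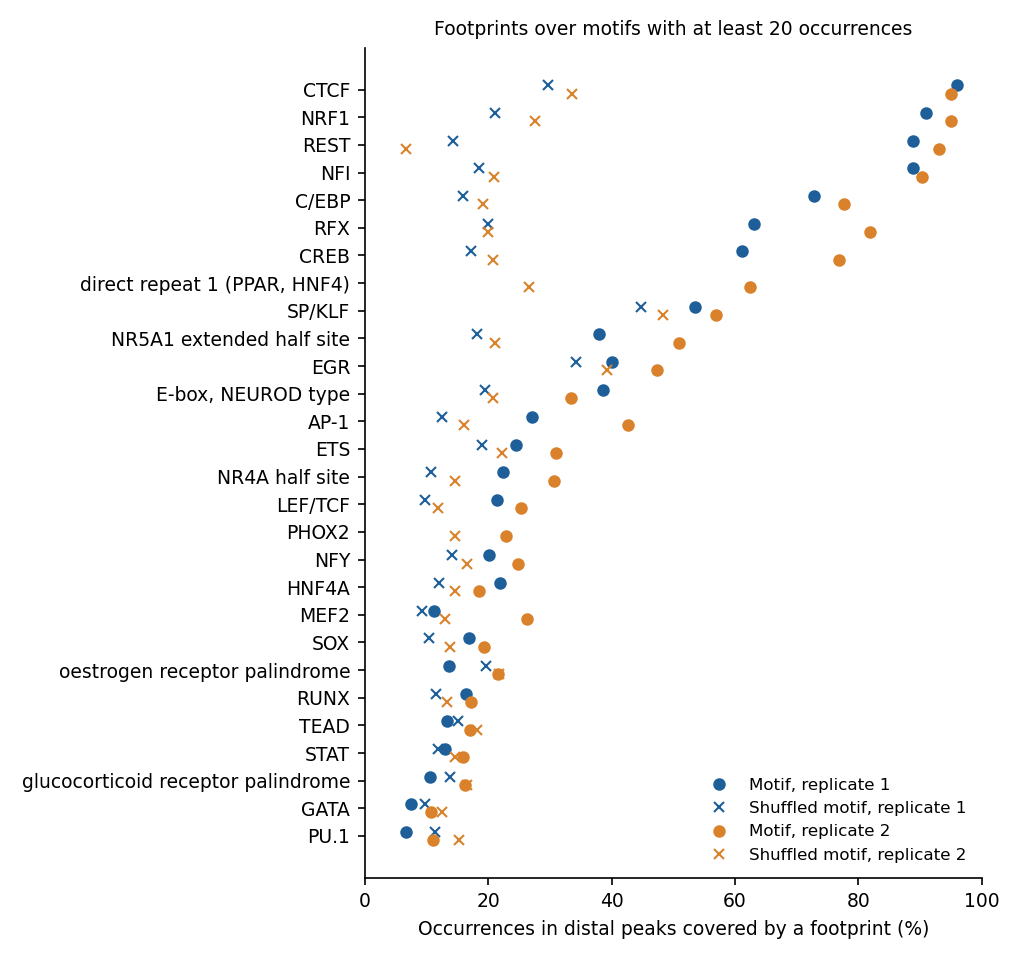
Share of motif occurrences in distal peaks that a footprint covered (percent, x axis), as points for each motif shown and crosses for its shuffles, in replicate 1 (blue) and replicate 2 (orange). CTCF lies at 96.0% and 95%, and the NR5A1 motif at 38.0% and 50.9%.

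Peaks of replicate 1 were largely found again in replicate 2, which had many more. Of the replicate 1 peaks, 65938 of 72643 (90.8%, 95% Wilson interval 90.6 to 91.0) overlapped a replicate 2 peak, against 2.59% ± 0.0548 (SD over 100 random placements). Of the replicate 2 peaks, 66967 of 157649 (42.5%, 42.2 to 42.7) overlapped a replicate 1 peak, against 1.19% ± 0.0286. With equal numbers of strongest peaks the shares were 76.8% and 77.9%. Over 63286 pairs that overlapped 1 to 1, heights had a Spearman rho of 0.902 and a Pearson r of 0.924 on the log2 scale. These correlations are across regions, which are not independent replicates. Replicate 2 was higher by a median of 1.00 on the log2 scale, with 0.82 at promoters and 1.08 at distal peaks. Dio2, Tcf21 and Hand2 were among the list genes open in replicate 2 only, and over all lists 31 members were open in replicate 2 only, 4 in replicate 1 only, 190 in both and 114 in neither. With equal numbers of strongest peaks these counts were 4, 22, 172 and 141, and 7 of the 22 were chromaffin genes. A gene in 2 lists was counted in each. The same switch was seen over all 21755 protein coding genes. There, 1128 were open in replicate 2 only and 80 in replicate 1 only, against 172 and 827 with equal numbers.

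**Figure D5:**
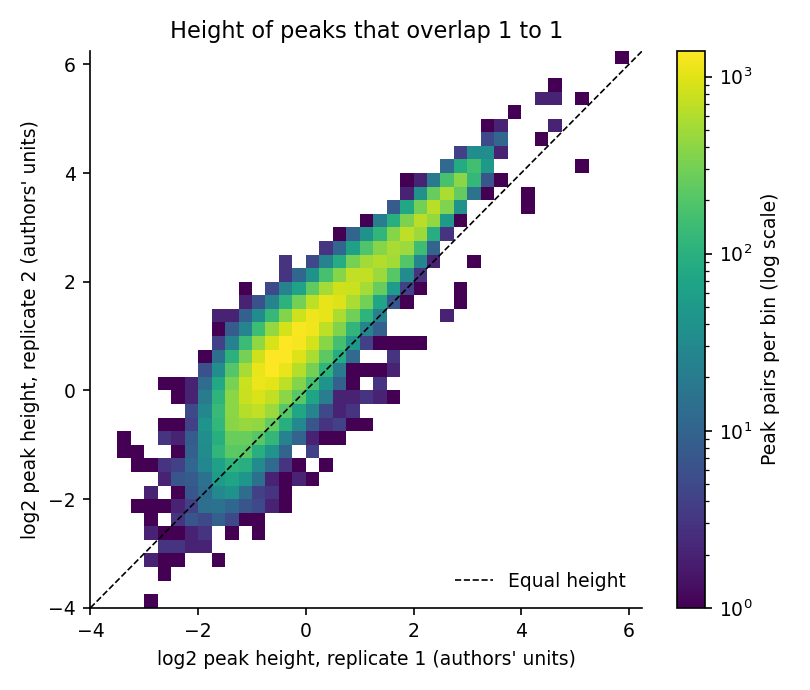
Number of peak pairs by log2 peak height in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units, for the 63286 pairs that overlapped 1 to 1. Most pairs lie above the dashed line of equal height, by a median of 1.00 on the log2 scale.

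Peaks found in a single replicate were mostly low. Replicate 1 had 6705 such peaks (9.23%), at a median percentile of 4.82, and replicate 2 had 90682 (57.5%), at a median percentile of 30.4. Among the highest decile of peaks, 5 of 7265 in replicate 1 and 120 of 15757 in replicate 2 were found in that replicate only. The longer list of the other replicate held 16.4% of the replicate 1 peaks and 34.5% of the replicate 2 peaks of this kind. The number in replicate 2 depended on list length and was 16084 with equal numbers of strongest peaks.

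Promoters were enriched among peaks in both replicates. Promoter peaks made up 28.4% of peaks in replicate 1 (95% Wilson interval 28.1 to 28.7) and 17% in replicate 2 (16.8 to 17.1), or 22.7% ± 8.09 (SD, n = 2), against 2.81% at random. The difference between replicates largely followed list length, since equal numbers of strongest peaks gave 28.4% and 26.1%. Exons held 7.41% and 6.68% (7.04% ± 0.517), against 5.00% at random. Introns held 35.9% and 43.7% (39.8% ± 5.5), against 41.6%, and intergenic regions 28.3% and 32.7% (30.5% ± 3.10), against 50.6%. Chromosome 11 had the most peaks per Mb, 47.2 and 92.8, and the X had 10.7 and 25.3.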

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

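The tests with windows and CpG matching at the outermost basic transcript start were chosen only after the results were seen. Of 865 comparisons of a result with its value under an alternative, 777 kept their call, stayed uncalled or stayed within the spread. Of the others, 22 lost a call, 42 gained one, 23 values moved and 1 called value changed sign. Some of these outcomes were fixed in advance. A call needed both replicates, so leaving 1 out could not lose it. Nor could that move a location share beyond the SD of the replicates. Equal numbers of strongest peaks left the list of replicate 1 as it was. The overlap share of replicate 1 was 89.4% with half-length overlap, 98.6% above the median height, 85.6% with the longer lists and 76.8% with equal numbers of strongest peaks, and that of replicate 2 was 41.7%, 46.6%, 44.8% and 77.9%. Equal numbers gave 16822 and 16084 peaks in a single replicate and a Spearman rho of 0.890, by construction of shorter lists, and 4166 replicate 1 peaks had no partner within 500 bp. The promoter share was 34.1% above the median height. Lists called lower at promoters numbered 2, with 3 to 4 when a replicate was left out (4 without replicate 1), 8 with unmatched lists and 5 above the median height. Lists called higher numbered 4, and 2 at the outermost gene end alone. The steroid synthesis call was lost at that end (70.0%) and with unmatched lists (90%), and the chromaffin list gained a call as lower above the median height (30.0%). Lists called higher by distal peaks numbered 3, with 4 to 6 when a replicate was left out (6 without replicate 1) and 5 above the median height. The NR5A1 motif lost its call above the median height at 2.56, over 20608 and 59125 distal peaks. It kept its call with equal numbers of strongest peaks, over 52021 and 53675. The TEAD footprint difference changed sign to 1.58 points when 1 bp of overlap was enough, as did the uncalled ones of the glucocorticoid receptor (1.90), the oestrogen receptor (1.06) and STAT (-0.338). At the outermost basic start all 4 higher and 2 lower promoter calls were kept, brain neurons were called lower too, and by distal peaks the glucocorticoid response lost its call (9.25) and cortex regulators gained one (8.5). Apart from the shorter lists with equal numbers of strongest peaks, the cause of these changes was not tested. The stronger footprints by the authors' value could not be taken, since that value is constant, and HNF1 footprints gave no value without replicate 2, because the motif did not occur in replicate 1. No paired analysis was possible because the series has 1 group. Depth is unknown, so the number of peaks sets what could be found in replicate 1.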

Other observations

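The tests of peak height above the floor, of the height step, of all motifs together, of GC content, of unequal amounts of fat and of chromaffin promoters open in replicate 1 only were chosen only after the results were seen. CTCF motif matches were concentrated in the highest distal peaks. In replicate 1 the share with the motif went from 0.903% in the lowest height decile to 15.2% in the highest. In replicate 2 it went from 1.28% to 15.2%. GATA motif matches went the other way, from 1.77% to 0.827% and from 2.78% to 1.34%. The NR5A1 share was 3.02% in the lowest and 3.79% in the highest decile of replicate 1, against 5.54% over all distal peaks. In replicate 2 these shares were 6.22%, 5.53% and 7.11%. In replicate 2, the NR5A1 motif was present in 6.41% of distal peaks shared with replicate 1 and in 7.50% of those found in replicate 2 only, while CTCF was present in 9.02% and 2.28%. In distal peaks found in replicate 1 only, some motifs were rarer, with CTCF in 0.144%, AP-1 in 3.20% and NR5A1 in 2.19%, against 9%, 14.9% and 5.95% of shared peaks. TEAD (3.11% against 3.24%), GATA (1.63% against 1.71%), PU.1 (1.18% against 1.22%) and RUNX (1.89% against 2.10%) were about as frequent, and SOX was more frequent (2.15% against 1.65%). Peaks found in replicate 1 only were mostly low, and height was not matched here. In the lowest height decile of all replicate 1 distal peaks, CTCF was present in 0.903%, AP-1 in 5.67%, NR5A1 in 3.02% and SOX in 2.27%.

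Peaks were more numerous in replicate 2. The 63286 pairs that overlapped 1 to 1 were higher there by a median of 1.00 on the log2 scale. Over all peaks of each list the median height was 0.863 in replicate 1 and 0.861 in replicate 2. The criterion set in advance for an even gain was met, since the largest deviation at matched height among 4 named motifs was 0.0714 (NFI, 95% bootstrap interval 0.03 to 0.13). A gain even over all peaks was still argued against by motifs looked at afterwards. Peaks with the EGR motif deviated by -0.37 (-0.43 to -0.30) and those with SP/KLF by -0.31 (-0.34 to -0.28). The GC-richest decile of distal pairs, with or without a motif, deviated by -0.32 at matched height. Motif and GC content were not separated. A preference for AT-rich peaks was argued against as the whole cause, because the GC-richest decile of distal pairs was still higher by 0.76 (0.75 to 0.78), though the gain did fall from 1.31 in the AT-richest decile. A deeper library may contribute and cannot be told apart: 92.9% of replicate 2 only peaks stood above the height of the lowest 5% of replicate 1 peaks, and the height step was 1.2 times that of replicate 1. Both values would argue against it if heights were scaled to the read total, since the larger step would then mean fewer reads in replicate 2, but the scaling factor is not stated. No biological explanation was tested, since both replicates belong to 1 group.

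Promoter peaks at fat cell genes may come from fat left on the gland, from fat genes that the gland itself uses, or from both. The median log2 promoter height ratio of replicate 2 over replicate 1 was 1.04 in the fat list, 0.28 above that of lists matched on mean height, at percentile 97.0 of random lists, inside their middle 95%, so unequal amounts of fat cannot be told apart from chance. The NR5A1 motif in distal peaks around fat genes had an odds ratio of 0.763 (95% exact interval 0.153 to 2.33) in replicate 1 and 0.544 (0.196 to 1.21) in replicate 2, too few peaks to exclude shared sites with steroid cells. Expression of these genes was not analysed here, and no further biological explanation was tested.

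The X chromosome had fewer and lower peaks. At distal peaks with the CTCF motif the median log2 height was lower on the X than on autosomes, by -1.10 (95% bootstrap interval -1.33 to -0.88) in replicate 1 and -1.16 (-1.40 to -0.94) in replicate 2, within the range set before the test for 1 copy. Over all distal peaks, for which no range was set, the difference was smaller, -0.63 and -0.74. The single X copy of male cells, the sex that the labels give, may contribute, and how much of the pattern it explains stays open. Fewer genes were argued against as the whole cause, because peaks per gene on the X were 0.542 and 0.591 times those on the autosomes. A part due to fewer genes stays open. Mappability was not tested and stays open, and sequence variants between the parental strains were not analysed on any chromosome.

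A different share of cortical cells between replicates was a hypothesis written before its test. Cortex minus chromaffin distal peaks differed in log2 height ratio by -0.0361 (95% bootstrap interval -0.15 to 0.21, over 191 and 47 pairs), too wide to exclude a modest difference in cell share. With equal numbers of strongest peaks, 7 of the 14 chromaffin promoters open in replicate 1 were open there only. Random genes matched on height in replicate 1 gave 4.82 on average and 2 to 7 in their middle 95%. The 13 chromaffin genes open in both replicates had a median log2 promoter height ratio of 0.572. Lists matched on mean height gave 0.347 to 0.938 in their middle 95%. A lower share of chromaffin cells in replicate 2 stays open. A second hypothesis was that NR5A1 sites may gather around steroid synthesis genes. The odds ratio of the motif in distal peaks there was 1.54 (95% exact interval 0.822 to 2.67) in replicate 1 and 1.5 (0.977 to 2.23) in replicate 2, with Fisher's exact p 0.127 and 0.0446 and adjusted p 0.794 and 0.558 over the lists, so it stays open.

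Entries that overlapped an earlier entry of the same peak list were nearly absent from chromosome 1. Only 1 of 4648 entries there overlapped an entry before it in replicate 1 and 0 of 10505 in replicate 2, against 2.07% and 0.980% on the other chromosomes (Fisher's exact p 1.73e-39 and 5.8e-44). These overlaps were merged before counting, and no explanation was tested.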
